A study of Mus musculus with 6 samples.

How the data were processed

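RNA was measured in dorsal pancreatic buds dissected from mouse embryos at stage E11.5 and kept in culture for 24 h. Each sample was a pool of 10 buds. Per the labels' protocols, total RNA was extracted with a silica column kit for small samples, amplified as cDNA by a linear isothermal method, fragmented, labelled with biotin and hybridised overnight to Affymetrix whole-transcript arrays, 1 sample per array. The labels state that quality metrics showed no outlying array. There were 6 arrays in 3 groups of 2: buds cultured with 0.1% DMSO as the control, with I-BET151 at 500 nM, or with JQ1 at 100 nM. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the pools of a group came from separate litters or culture days, so p-values measure the spread between these pools, which may be partly technical.

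The deposited values are intensities on a linear scale, normalized by the authors with RMA (robust multi-array average: background correction, quantile normalization between arrays and a summary over probes), per the submitters' processing notes, which give no version. The table holds 24972 rows of whole numbers, from 5 upward, with a median of 54 to 57 on each array. How probes were combined per gene, and how the values were returned to a linear scale and rounded, is not given in the sources used here. RMA removes differences in the total signal between arrays, so a change shared by most transcripts would not be seen. Rounding leaves coarse steps among dim genes: 257 named genes had equal values within every pair of replicates, and such genes lower the estimate of how alike the genes' variances are. There are no detection calls, and 84 named genes lay at the lowest value of 5 on at least 1 array. For arrays, depth has no count equivalent, and 2 arrays per group limit the precision.

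Rows were named through the platform's probe annotation. Of the 24972 rows, 24014 had 1 gene symbol, none had several, and 958 were not listed there and stayed unnamed here, so the genes behind them were not analysed here by name. The row identifier was the Entrez gene ID for every listed row, and 23921 of these IDs were found in a RefSeq gene table of the assembly GRCm38.p6, used for names, gene classes and gene spans only. For 4 symbols with more than 1 row, the row with the highest mean was kept, which left 24010 genes. No coordinates are given, because the sources used here name no genome build for the arrays.

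From these values, log2(intensity) was computed with no pseudocount and no filter, and limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with its default prior) was fitted to all 6 arrays at once, so that the 3 groups shared one estimate of the spread. The fit had 3 residual degrees of freedom, to which the prior added 1.76. The contrasts tested were each inhibitor against control, I-BET151 against JQ1, and the mean of both inhibitors against control. P-values were adjusted by the Benjamini-Hochberg method over 24010 genes in each contrast, and a gene was called at an adjusted p under 0.05. "Rose" and "fell" are used of called genes only. Values are group means of the intensity ± SD with n = 2, and log2 changes ± SE from the fit. Intervals are 95% intervals from the fit for single genes, with no adjustment for the number of genes.

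Before the data were examined, 33 gene lists were fixed, covering pancreatic cell types, other cell types that a bud can hold, signalling pathways, the cell cycle, metabolism and genes known to respond to BET inhibitors. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list with all other genes, and adjusted over the 33 lists. The same test with an estimated correlation, and fry, which asks whether the genes of a list move one way without comparing them with other genes, were run beside it. Counts of called list members are those of each inhibitor against control unless the mean of both is named. Named genes followed a rule fixed at the same time: the 10 largest rises and the 10 largest falls for each inhibitor among called genes whose arrays did not overlap with the controls, the 5 largest each way between the inhibitors, 15 genes named whatever they did, and up to 4 members of each list with the smallest p. Predicted genes, small RNAs and olfactory or vomeronasal receptors were counted but not named by that rule. Of the 15 genes, 13 had a named row, and the others are not reported here.

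The fit was tested on simulated data with 200 of 24010 genes changed, in 10 draws. The changed genes were drawn only from those brighter in the controls than a cut close to the array median. The share found among dimmer genes was not tested. For I-BET151 against control, it found 52.0% of genes changed by 1 on the log2 scale and 3.4% of genes changed by 0.5, with 1.2 false calls per draw on average. For JQ1 against control, the shares were 53.9% and 3.4%. A list shifted by 0.25 was found in 10 of 10 draws for both inhibitors, and with an estimated correlation in 6 draws for I-BET151 and in 8 for JQ1. Noise in these draws was independent between genes. They therefore do not test how list calls at the preset correlation hold where genes vary together. Because both inhibitors were compared with the same 2 control arrays, unchanged groups sharing those controls were simulated 100 times for correlations and 20 times for overlaps of calls.

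Alternatives covered the scaling between arrays, a filter on dim genes, the handling of repeated and unnamed rows, the prior of the fit, array weights, the groups in the fit, the replicate number as a block, leaving out each array in turn, and the threshold. Alternatives that reduce the effect of rounding, by adding random numbers within 0.5 of the deposited value or leaving out genes below the median intensity, were added after the data had been seen.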

Results

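Expression was profiled in mouse dorsal pancreatic buds from stage E11.5 after 24 h of culture with DMSO, I-BET151 or JQ1. Both compounds block the bromodomains of the BET proteins, chromatin readers that bind acetylated histones and recruit the transcription elongation machinery. At this stage the bud holds an epithelium of multipotent progenitors and early endocrine cells within mesenchyme, vessels and nerve precursors. The comparison asks which genes of the early pancreas respond when BET proteins are inhibited. There were 2 arrays per group, each from a pool of 10 buds, and the median intensity of the arrays lay between 54 and 57. Arrays of one group correlated at 0.995 to 0.996 across the 24010 named genes on the log2 scale, and control against treated arrays at 0.990 to 0.993. I-BET151 against JQ1 arrays correlated at 0.995 to 0.996, as highly as replicates did. The first principal component, with 49.1% of the variance, placed both control arrays on one side and all 4 treated arrays on the other.

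Under 500 nM I-BET151, 272 of 24010 genes changed, of which 63 rose and 209 fell. The largest falls included Cckar, Slc2a2 and Postn. Cckar, the cholecystokinin A receptor, went from 359.5 ± 54.4 to 58.0 ± 11.3 (SD, n = 2), 6.22-fold lower. Slc2a2, the glucose transporter of beta cells and hepatocytes, went from 599.5 ± 78.5 to 112 ± 18.4, 5.37-fold lower, with a log2 change of -2.42 ± 0.15 (SE, limma adjusted p = 0.0306). Postn, which encodes the matrix protein periostin, fell 3.83-fold from 519.5 ± 43.1 to 136 ± 17.

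The other largest falls under I-BET151 were Wfdc15b (5.13-fold lower), the adhesion receptor gene Adgrg6 (3.86-fold), the hyaluronan link protein gene Hapln1 (3.59-fold), the nucleoside transporter gene Slc28a3 (3.56-fold), Clca3a1 (3.30-fold), the pancreatic lipase-related gene Pnliprp1 (3.08-fold) and Tac2, which encodes neurokinin B (3.05-fold). Of the 209 genes that fell, 68 did so by 2-fold or more. Rises were smaller. Gpr137c rose 2.80-fold from 72.0 to 202 ± 7.07, and Tc2n 2.67-fold. H2bc4, a replication-dependent histone H2B gene, rose 2.66-fold from 581 ± 17 to 1546 ± 12.7, and the magnesium transporter gene Cnnm4 2.42-fold. Rises of 1.80-fold to 1.92-fold were measured for Spata2l, Habp4, Ildr2, Gpr21, the myosin gene Myo6 and Frmd6. Hexim1, which encodes an inhibitor of the elongation kinase P-TEFb and is a widely used marker of BET inhibition, rose 1.59-fold (adjusted p = 0.0432). Histone genes are near-identical copies of one another, so the array cannot fully separate H2bc4 from its paralogues.

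All 272 genes had both I-BET151 arrays on one side of both control arrays. A call with so few arrays nearly requires this, so it is no separate support. Of all genes, 42.1% had their arrays placed so, and chance gives 33.3%. The count rests on having all 6 arrays: without any 1 of them, whether CTRL 1, CTRL 2, I-BET151 1, I-BET151 2, JQ1 1 or JQ1 2, no gene passed, whereas with genes below the median intensity also left out 377 to 1042 genes passed in these 6 fits. With rounding dithered instead, 0 to 420 passed, with 0 without CTRL 2. With each array centred on its median, 179 genes rose and 379 fell.

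Under 100 nM JQ1, 912 genes changed, of which 272 rose and 640 fell. Cckar again had the largest fall, from 359.5 ± 54.4 to 34 ± 4.24 (10.6-fold lower, log2 change -3.40 ± 0.19, adjusted p = 0.0112), and Slc2a2 fell 7.85-fold to 76.0. Serpina6, which encodes corticosteroid-binding globulin, fell 5.91-fold from 1790.5 ± 193 to 315.5 ± 128, with a wide SE of 0.41 on the log2 scale. The RNA-binding factor gene A1cf fell 4.96-fold, and Fabp7, a marker of glia and their precursors, fell 4.81-fold from 812 ± 24.0 to 169.5 ± 21.9.

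Wfdc15b, Adgrg6, Slc28a3, Pnliprp1 and Postn completed the 10 largest falls under JQ1, each by 4.74-fold to 5.61-fold. The largest rises were Hspa1a (4.20-fold, from 83.0 ± 5.66 to 348.5 ± 13.4) and Hspa1b (3.47-fold), which encode inducible heat shock proteins and are near-identical copies that the array cannot fully separate. Tc2n (3.30-fold), Gpr137c (3.29-fold), H2bc4 (3.26-fold), Cnnm4 (3.08-fold), the histone genes H2aw (2.81-fold) and H2bc8 (2.39-fold), the metallothionein gene Mt2 (2.38-fold) and Frmd6 (2.35-fold) followed. Hexim1 rose 2.00-fold, from 640.5 ± 21.9 to 1283.5 ± 29.0 (log2 change 1.00 ± 0.07, adjusted p = 0.0143).

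All 912 genes had both JQ1 arrays on one side of the controls, which a call again nearly requires, and 44.9% of all genes did. Without any 1 of the 6 arrays, again each in turn, no gene passed, and with genes below the median intensity also left out 951 to 2205 did (222 to 1081 with rounding dithered instead). The excess of falls depended on the scaling: with each array centred on its median, 704 genes rose and 753 fell.

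**Figure D1:**
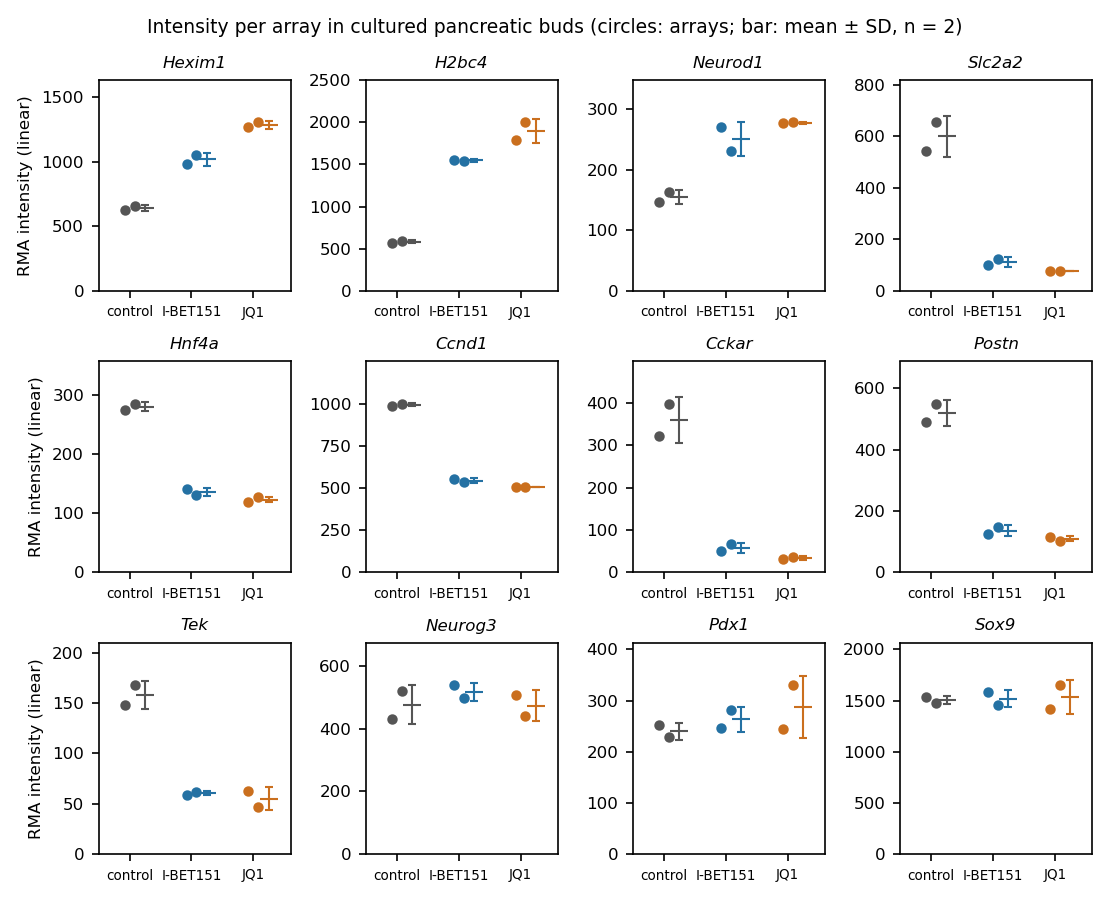
RMA intensity on a linear axis for 12 genes in control, I-BET151 (500 nM) and JQ1 (100 nM) buds, with circles for single arrays and a bar for the mean ± SD (n = 2). Cckar stood at 359.5 in the controls, 58.0 under I-BET151 and 34 under JQ1, while Neurog3, Pdx1 and Sox9 were not called under either compound.

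Among the transcription factors of the pancreatic epithelium, Hnf4a fell under both inhibitors, from 281 ± 7.07 to 136.5 ± 6.36 under I-BET151 (log2 change -1.04 ± 0.07, adjusted p = 0.0313) and to 123.5 ± 4.95 under JQ1 (-1.19 ± 0.07, adjusted p = 0.0112). Mnx1 rose 1.58-fold under JQ1 and stood at 1.55-fold under I-BET151, where it was not called (adjusted p = 0.0755). The endocrine factor Neurod1 rose 1.79-fold under JQ1, from 155.5 ± 12 to 278 ± 1.41, and stood at 1.61-fold under I-BET151, where it was not called (adjusted p = 0.0702). Sox11 rose 1.42-fold under JQ1 and was at the same ratio, not called, under I-BET151. The endocrine determinant Neurog3 was measured at 476 ± 62.2, 518.5 ± 29.0 and 473.5 ± 48.8 in control, I-BET151 and JQ1 buds, and neither change was called. Pdx1, Ptf1a, Sox9 and Nkx6-1, which mark progenitors, had log2 changes between 0.01 and 0.24 that were not called. Gcg, the glucagon gene, was abundant (5486 ± 11.3 in controls) and not called, nor were Cpa1 and Serpini1, and Ins2 lay near the floor at 9 to 10.

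The lists of pancreatic progenitor genes (19 measured), endocrine progenitor genes (21) and islet hormone and secretory genes (29) were not shifted under either inhibitor, with camera adjusted p of 0.158 to 0.803. Slc2a2 was the only called member of the islet list. The endocrine progenitor list, adjusted over the list alone, had 3 rises and 2 falls under I-BET151 and 3 and 3 under JQ1. The progenitor list had 1 rise and 1 fall under each inhibitor, and the islet list 1 fall under each.

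Acinar and ductal genes were lower. Of 31 acinar genes, 1 fell under I-BET151, Pnliprp1, and 5 fell under JQ1: Pnliprp1, Clps, Ctrb1, Reg1 and Cel, the last chosen after its values were seen. The Reg1 row was dim, at 30 and 28 on the control arrays and 10 on both JQ1 arrays. Clps, which encodes colipase, went from 475 ± 26.9 to 242.5 ± 12 under JQ1, and Ctrb1, a chymotrypsinogen gene, from 1060 ± 77.8 to 604 ± 29.7. Over 31 genes, 3 and 7 fell when adjusted over the list alone. The list was shifted down under both (camera adjusted p = 0.0145 and 4.68e-05, and adjusted p = 0.369 and 0.233 with an estimated correlation), but under I-BET151 it passed no longer without CTRL 2 (0.120). Of 18 duct and epithelial trunk genes, Anxa4 and Cldn3 fell under both, Cldn3 from 741 ± 7.07 to 391.5 ± 50.2 and 370, and Krt18 fell under JQ1. Of these genes, 3 fell under I-BET151 and 5 under JQ1 adjusted over the list alone, and the list was shifted down (adjusted p = 0.00661 and 0.00180, and adjusted p = 0.259 and 0.233 with an estimated correlation).

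Markers of the tissue around the epithelium were also lower. Among 27 mesenchyme markers, Postn and Dcn fell under both inhibitors and Prrx1 and Meox1 under JQ1. Dcn, which encodes the proteoglycan decorin, went from 308.5 ± 9.19 to 126.5 ± 13.4 and 86.5 ± 14.8. Under each inhibitor 11 fell adjusted over the list alone (list adjusted p = 0.000216 and 1.45e-05, and adjusted p = 0.186 and 0.182 with an estimated correlation). Among 19 endothelial markers, Tek and Eng fell under I-BET151 and 8 fell under JQ1, including Emcn and Pecam1. Tek, the angiopoietin receptor gene, went from 158 ± 14.1 to 60.5 ± 2.12 and 55 ± 11.3. The median endothelial change was -0.33 and -0.46, and adjusted over the list alone 11 and 16 fell, and 1 rose under I-BET151 (list adjusted p = 2.19e-08 and 4.82e-12, and adjusted p = 0.186 and 0.182 with an estimated correlation). Ednrb and Stmn2 fell under both inhibitors and Fabp7 under JQ1 among 15 neural and neural crest markers. Under each inhibitor 4 of these fell adjusted over the list alone (list adjusted p = 0.000301 and 0.00215, and adjusted p = 0.186 and 0.233 with an estimated correlation).

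Other cell types were less uniform. The 14 macrophage and immune markers were not shifted (adjusted p = 0.910 and 0.443), and none was called; adjusted over the list alone, 2 rose and 2 fell under I-BET151, and 1 rose and 3 fell under JQ1. Liver markers (13) were not shifted as a list (adjusted p = 0.226 and 0.383), and none was called by either adjustment under I-BET151 or JQ1. Abundant members nevertheless had lower means with a wide spread: Serpina1b was at 1488 ± 8.49, 640.5 ± 233 and 576.5 ± 129 in control, I-BET151 and JQ1 buds, Fgb at 289.5 ± 23.3, 103 ± 28.3 and 109 ± 49.5, and Trf at 653.5 ± 33.2, 422 ± 107 and 440.5 ± 139. For the mean of both inhibitors, Serpina1b and Fgb fell adjusted over the list alone but not over all genes (adjusted p = 0.0613 and 0.0741). Serpina1b has near-identical copies that the array may not separate. Slc2a2 and Hnf4a, which fell under both inhibitors, and Serpina6 and A1cf, which fell under JQ1, are also expressed in liver. Erythroid markers (11) were shifted down under I-BET151 (adjusted p = 0.0158, and adjusted p = 0.369 with an estimated correlation), which ended without CTRL 2 (0.360) or without I-BET151 1, and not under JQ1 (adjusted p = 0.260), with no call for the difference between the compounds (adjusted p = 0.224). Of these, 2 and 1 fell adjusted over the list alone. The 10 mesothelium markers (adjusted p = 0.615 and 0.754) and 14 stomach and intestine markers (adjusted p = 0.707 and 0.656) were not shifted. Upk3b fell 2.19-fold under JQ1, and Vil1, the villin gene, fell under both. The Vil1 row was dim, at 26 and 28 on the control arrays, 17 and 16 under I-BET151 and 18 and 19 under JQ1. Under each inhibitor 2 mesothelium markers rose while 1 and 2 fell, and 1 gut marker fell, all adjusted over the list alone.

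Cell cycle genes were lower as a group, by small amounts each. All 31 G2 and M phase genes had negative log2 changes under both inhibitors, with medians of -0.27 each. Plk1, a mitotic kinase gene, went from 1606 ± 63.6 to 1204.5 ± 26.2 and 1228 ± 29.7, and fell under JQ1 together with Nusap1 and Nuf2. Adjusted over the list alone, 21 fell under I-BET151 and 10 under JQ1 (list adjusted p = 1.54e-12 and 8.20e-11, and adjusted p = 0.259 and 0.242 with an estimated correlation). None of the 28 S phase genes was called under I-BET151 or JQ1, over all genes or adjusted over the list alone, with medians of -0.18 and -0.16 (list adjusted p = 7.92e-06 and 4.72e-06, and adjusted p = 0.259 and 0.233 with an estimated correlation), or -0.14 and -0.09 with each array centred on its median. For the mean of both inhibitors, Fen1 and Mcm3 fell in the S phase list (log2 changes of -0.32 and -0.33, adjusted p = 0.0456 and 0.0459). The cyclin gene Ccnd1, listed among 13 Wnt targets, fell from 993 ± 8.49 to 544 ± 15.6 and 505.5 ± 2.12, while the Wnt list was not shifted (adjusted p = 0.924 and 0.260; adjusted over the list alone, 2 and 1 fell).

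Myc was at 671.5 ± 13.4, 448.5 ± 27.6 and 483.5 ± 31.8 in control, I-BET151 and JQ1 buds, and missed the threshold under each inhibitor alone (adjusted p = 0.060 and 0.0539). It passed for the mean of both, with a log2 change of -0.53 (adjusted p = 0.0310). The 30 genes of Myc and its growth targets were shifted down, with medians of -0.22 and -0.16 (adjusted p = 1.65e-07 and 2.93e-05, and adjusted p = 0.205 and 0.233 with an estimated correlation), or -0.18 and -0.09 with each array centred on its median. Over all genes, Utp20 fell under JQ1, and Utp20, Myc and Ldha fell for the mean of both. The counts adjusted over the list alone were 9 falls under I-BET151 and 3 under JQ1. In the list of 19 p53 targets, Ccng1 and the cell cycle inhibitor gene Cdkn1a fell under both inhibitors, Cdkn1a from 1092.5 ± 31.8 to 697 ± 50.9 and 681.5 ± 2.12, and Sesn2 rose under JQ1. In this list 7 fell under each, and 1 and 2 rose, adjusted over the list alone (list adjusted p = 0.00237 and 0.00181, and adjusted p = 0.196 and 0.233 with an estimated correlation).

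Cholesterol synthesis genes (17 measured) had medians of -0.33 and -0.47, and Fdft1, Nsdhl, Sc5d and Stard4 fell under JQ1. Of the 17 genes, 5 and 11 fell adjusted over the list alone (list adjusted p = 7.89e-06 and 2.30e-07, and adjusted p = 0.292 and 0.233 with an estimated correlation). Among 20 interferon response genes, Bst2 fell under both inhibitors, and Ddx58 and Ifih1, sensors of viral RNA, fell under JQ1. Adjusted over the list alone, 6 fell under each (list adjusted p = 0.000117 and 0.00124, and adjusted p = 0.186 and 0.233 with an estimated correlation). The 68 oxidative phosphorylation genes had medians of -0.10 and -0.06 and none was called by either adjustment under I-BET151 or JQ1. This list passed weakly (adjusted p = 0.000392 and 0.0385, and adjusted p = 0.369 and 0.602 with an estimated correlation). Under I-BET151 it was lost without CTRL 1 (0.0766). Under JQ1 it was lost without CTRL 1 (0.579), JQ1 1 (0.115) or JQ1 2 (0.0568), without the dimmest 25% of genes (0.0848) and with each array centred on its median (0.106), where its median also turned to 0.01. Hypoxia and glycolysis genes (19) were shifted down under I-BET151 (adjusted p = 0.0268, and adjusted p = 0.456 with an estimated correlation), which ended without I-BET151 1 (0.232) or CTRL 2, and under JQ1 the adjusted p was 0.248. The difference between the compounds was not called for this list (adjusted p = 0.224). Egln3 fell and P4ha1 rose in that list under JQ1. There, 5 genes fell under each inhibitor, and 2 and 4 rose, adjusted over the list alone.

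Among the 33 lists, upward shifts against control were found for genes known to respond to BET inhibitors and, under JQ1, for histone genes. Both lists hold H2bc4 and H2aw, so these shifts are not independent. Of 12 genes known from other systems to rise under BET inhibitors, H2bc4 and Hexim1 rose under I-BET151, and H2aw and Txnip joined them under JQ1. Adjusted over the list alone, 7 rose under I-BET151, and 6 rose and 1 fell under JQ1 (list adjusted p = 6.34e-05 and 1.64e-05, and adjusted p = 0.186 and 0.182 with an estimated correlation). Among 39 replication-dependent histone genes, H2bc4, H2aw, H2bc8 and H2bc6 rose under JQ1 and H2bc4 under I-BET151. This list was shifted up under JQ1 (median 0.29, adjusted p = 0.000324, and adjusted p = 0.437 with an estimated correlation), and under I-BET151 it missed the threshold (median 0.14, adjusted p = 0.0605). Against the mean of the controls, the histone median was 0.148 in CTRL 1 and -0.148 in CTRL 2, a gap larger than the values in the JQ1 arrays (0.233 and 0.247). The list p under JQ1 ranged from 7.17e-07 without CTRL 1 to 0.0447 without CTRL 2. Adjusted over the list alone, 3 rose and 1 fell under I-BET151, and 8 rose and 1 fell under JQ1. The 10 genes of BET proteins and P-TEFb were not shifted (adjusted p = 0.0718 and 0.0690). Brd2 was at 585.5 ± 13.4, 670 ± 17 and 742.5 ± 6.36 and missed the threshold (adjusted p = 0.181 and 0.0522), and Brd3 had log2 changes of 0.02 and -0.01. Adjusted over the list alone, 1 gene rose under I-BET151, and 3 rose and 1 fell under JQ1.

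The 8 lists that follow were not shifted by camera. Among 19 FGF and ERK feedback genes, Il17rd rose under both inhibitors and Spry1 under I-BET151 (list adjusted p = 0.129 and 0.0788), and adjusted over the list alone 2 and 4 rose. Mfng was the only called gene of the Notch pathway (23 genes) and fell under JQ1 (list adjusted p = 0.561 and 0.248), and adjusted over the list alone 1 and 2 fell. Axl fell under JQ1 among 13 Hippo targets (list adjusted p = 0.949 and 0.162; adjusted over the list alone, 2 rose and 2 fell, then 4 rose and 1 fell). Of 38 Hox cluster genes, Hoxa3 rose and Hoxd8 fell under JQ1 (list adjusted p = 0.158 and 0.0543), and adjusted over the list alone 1 and 3 rose and 1 fell under each. Egr1 rose under JQ1 among 20 immediate early genes (list adjusted p = 0.949 and 0.260), and adjusted over the list alone 1 and 2 rose. No TGF-beta or BMP target of 19 was called (list adjusted p = 0.0682 and 0.296), although adjusted over the list alone 2 rose and 3 fell under I-BET151. Rpl19 rose under JQ1 and was the only called gene, also adjusted over the list alone, of 58 ribosomal protein genes (list adjusted p = 0.0980 and 0.430). Its row was dim, at 25 and 26 on the control arrays and 39 and 36 on the JQ1 arrays, below the median intensity of every array. In the unfolded protein response list (20 genes, adjusted p = 0.151 and 0.516), Herpud1 fell and Sesn2 rose under JQ1, and adjusted over the list alone 1 rose and 1 fell under each inhibitor.

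By fry, 13 lists moved one way under I-BET151 and 17 under JQ1, of which 11 and 12 were among the 15 and 14 found by camera. Lists that passed fry alone were BET proteins and P-TEFb (fry adjusted p = 0.0123 and 0.00338) and FGF and ERK feedback genes (0.0334 and 0.0168). Under JQ1 the Wnt (0.0261), Hippo (0.0168) and Hox (0.0359) lists also did. Oxidative phosphorylation genes passed camera but not fry (0.153 and 0.309). So did histone genes under JQ1 (0.0846) and, under I-BET151, acinar (0.0858), erythroid (0.218) and hypoxia genes (0.153). With an estimated correlation none of the 33 lists passed under either inhibitor.

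**Figure D2:**
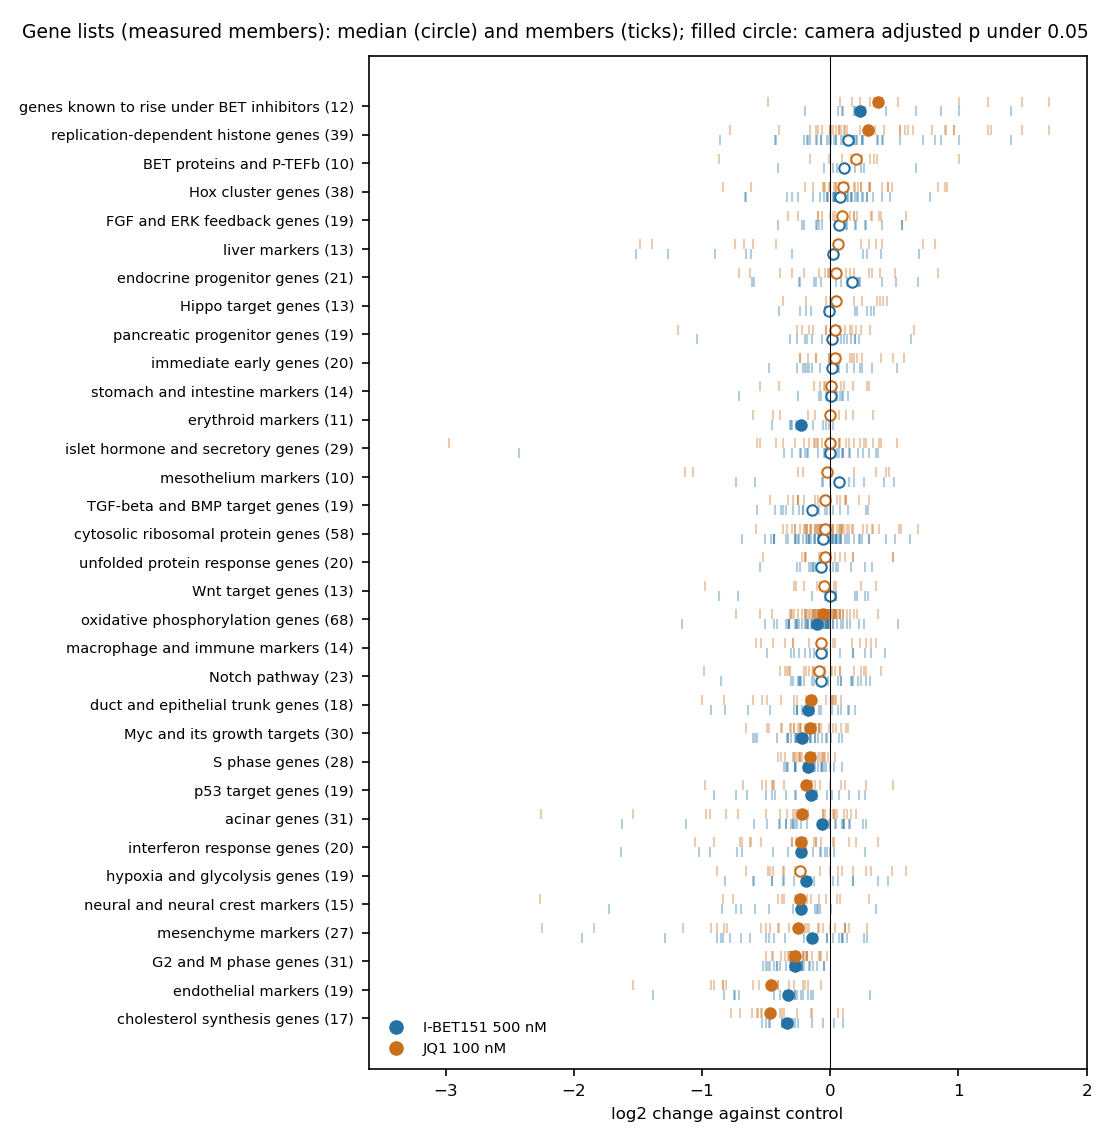
Log2 change against control for the measured members of the 33 gene lists (ticks) and their medians (circles), for I-BET151 at 500 nM and JQ1 at 100 nM, with filled circles for lists that passed camera at the preset correlation (none passed with an estimated one). Endothelial medians lay at -0.33 and -0.46 and those of genes known to rise under BET inhibitors at 0.23 and 0.37, while the oxidative phosphorylation median under JQ1 turns positive with each array centred on its median.

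Taking the mean of both inhibitors against control, 1181 genes changed, 382 up and 799 down. With each array centred on its median, 846 rose and 887 fell. Of the genes called for both compounds separately, 59 rose in both, 203 fell in both and none went opposite ways. Independent lists of these sizes would share 0.714 risen and 5.57 fallen genes, and 20 simulations of unchanged groups with shared controls gave at most 1 gene called in both. The 2 control arrays cannot be split into parts of 2 arrays each, so part of the excess in these counts may come from the shared controls. Of the I-BET151 calls, 96.3% were also called with JQ1. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.834, against 0.50 in simulations without any effect. Their covariance was 0.0578 against 0.00855 simulated, a difference of 0.0492. With 1 control array for each compound, tried both ways after the data were seen, no control was shared and the covariance was 0.0469 and 0.0487 (r = 0.586 and 0.620). Without any 1 of the 6 arrays in turn, no gene passed for the mean of both, and with genes below the median intensity also left out 1001 to 2316 did (194 to 1068 with rounding dithered instead).

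**Figure D3:**
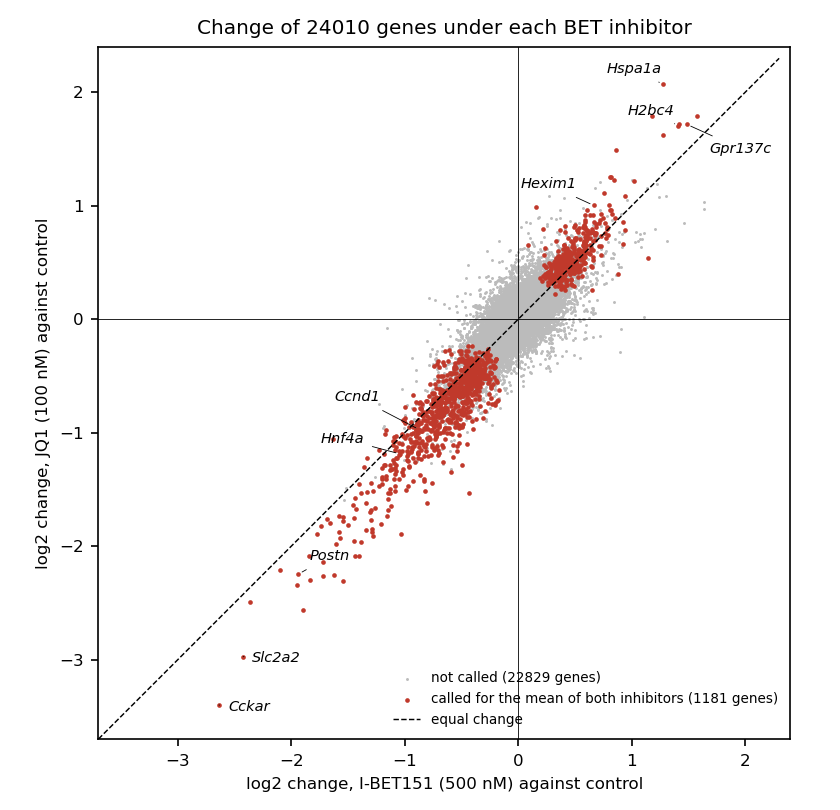
Log2 change against control under I-BET151 at 500 nM (horizontal axis) and JQ1 at 100 nM (vertical axis) for 24010 genes, where each point is a gene and the dashed line marks equal change. The 1181 genes called for the mean of both inhibitors (red) lie in the quadrants of shared direction, as selection on the mean of both axes favours, and both axes use the same 2 control arrays, which alone gives r = 0.50.

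Direct comparison of the compounds, which differ in scaffold (JQ1 is a thienotriazolodiazepine, I-BET151 an imidazoquinolinone bearing a dimethylisoxazole), was made at different doses, 500 nM I-BET151 and 100 nM JQ1. No gene differed between them in the limma fit (smallest adjusted p = 0.718), and 6 genes passed with an intensity trend and a robust prior. Of 24010 genes, 1610 had an unadjusted limma p under 0.05, a cut that a share of 0.05 of unchanged genes would pass. The arrays of the compounds did not overlap for 28.5% of all genes, and chance gives 33.3%. Among the 1181 genes changed by the mean of both, 940 (79.6%) had the larger change under JQ1, with a median absolute log2 change of 0.64 against 0.53 and a median ratio of 1.20. For Cckar, I-BET151 minus JQ1 was 0.76 on the log2 scale (95% interval 0.26 to 1.26), for Hexim1 -0.34 (-0.51 to -0.16) and for the colipase gene Clps 0.57 (0.37 to 0.77), none past the adjusted threshold. For Hnf4a it was 0.14 (-0.03 to 0.32), for Myc -0.11 (-0.32 to 0.10) and for Neurog3 0.13 (-0.20 to 0.47). These intervals leave room for differences of either sign in Hnf4a, Myc and Neurog3, and do not show that the compounds act alike. By camera, 5 of the 33 lists differed between the compounds, among them histone genes (35 of 39 lower with I-BET151, adjusted p = 0.000212) and endothelial markers (17 of 19 higher with I-BET151, adjusted p = 0.000129). None of the 5 passed with an estimated correlation (adjusted p = 0.571 for histone genes and adjusted p = 0.543 for endothelial markers with an estimated correlation) or by fry.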

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

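The test of macrophage content and the fits of lists between the compounds under other settings were chosen only after the result was seen. The tests of endothelial content were fixed before their results.

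Between the compounds, 5 gene lists differed by camera with a preset correlation, and none did with an estimated one. The median log2 difference, I-BET151 minus JQ1, was -0.178 for genes known to rise under BET inhibitors (adjusted p = 0.0156, and adjusted p = 0.543 with an estimated correlation). For replication-dependent histone genes it was -0.185 (adjusted p = 0.000212, and adjusted p = 0.571 with an estimated correlation). For acinar genes it was 0.118 (adjusted p = 0.000927, and adjusted p = 0.543 with an estimated correlation), and for cholesterol synthesis genes 0.114 (adjusted p = 0.0138, and adjusted p = 0.571 with an estimated correlation). For endothelial markers it was 0.129 (adjusted p = 0.000129, and adjusted p = 0.543 with an estimated correlation). Without 1 array, 4 of these 5 differences missed the threshold in at least 1 fit: genes known to rise under BET inhibitors without I-BET151 1 (0.133), JQ1 1 (0.0731) or JQ1 2 (0.0707), histone genes without I-BET151 1 (0.0766), acinar genes without JQ1 1 (0.0953), and cholesterol synthesis genes without I-BET151 2 (0.222) or JQ1 2 (0.0707). In each of these lists the median change against control was the larger under JQ1. The doses differed, so compound and dose cannot be separated in these lists. For histone genes a difference between libraries was not tested and stays open as well. Their medians against the mean of the controls were 0.0265 and 0.181 in the I-BET151 arrays and 0.233 and 0.247 in the JQ1 arrays. Over all 6 arrays, controls included, these medians ran in the same order as those of small nucleolar RNA genes, described below.

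Rows with no gene name here also responded. Of 958 such rows, 42 passed the threshold for the mean of both inhibitors, 14 higher and 28 lower, which is 4.38% against 4.81% of the named genes in the same fit of every row, where 1198 genes and rows passed in all.

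Endothelial markers were lower in treated buds, with a median of -0.39 for the mean of both inhibitors and 18 of 19 markers below 0. A candidate explanation is that treated buds held fewer endothelial cells, which would lower all markers alike. The SD of the 19 changes was 0.348, above 0.190, the upper bound in simulations of a common change with the fitted errors, and the changes ranged from -1.46 (Tek) to 0.02 (Sox7). The value of Sox7 averages opposite changes: it was at 349 and 323 on the control arrays, 421 and 412 under I-BET151, and 272 and 281 under JQ1. Markers that other cells of the bud also express would spread in the same way, so fewer endothelial cells and lower expression per cell cannot be told apart. The direct effect of BET inhibition on these genes was not tested.

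Msr1, Tlr13, Fcrls and Fcgr1, which macrophages express and which were singled out after their values were seen, fell for the mean of both inhibitors by 1.28 to 1.67 on the log2 scale (adjusted p = 0.00957 to 0.0195). Fewer macrophages would lower the other markers too, but the median of the 14 fixed macrophage markers was -0.0748, with a bootstrap interval of -0.296 to 0.173, above -0.683, which is 50% of the median change of those genes. The most abundant markers of the list, C1qb, Cd68 and Fcer1g, had changes of 0.31, -0.36 and 0.17, and none was called. None of the 14 is a member of another list. Adjusted over the list alone, 3 of the 14 rose and 3 fell for the mean of both inhibitors. These values argue against fewer macrophages as the whole cause of the falls of Msr1, Tlr13, Fcrls and Fcgr1. A milder loss of macrophages was not tested, because the bound was set from genes singled out after their values were seen. A change of expression within macrophages may remain, as a hypothesis.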

How the results depend on the processing

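Alternatives that reduce the effect of rounding or add an intensity trend without the robust prior, those that split the controls, and the list tests between the compounds and for the mean of both were chosen after seeing the data. No called value of a named gene changed direction, and no shifted list did in its camera test in any of the 4 comparisons, although the oxidative phosphorylation median under JQ1 changed sign with median centring. For genes called in the main fit, leaving out 1 array could not reverse the direction. Their treated arrays all lay on one side of the controls, so this is no separate support. The counts of called genes depended strongly on the setting. Plain fits without 1 array gave 0 genes in each comparison, from 0 to 0, and so did the fit of only the groups compared (0 for both inhibitors) and the replicate block (0 in all comparisons). Rounding to whole numbers leaves genes with no spread, so that the prior added only 1.76 degrees of freedom with 6 arrays and as few as 1.08 with 5. With rounding dithered the prior added 3.85 and gave 601 genes for I-BET151. Without the dimmer genes (those below the median intensity) it added 3.98, and 1422, 2362 and 2675 genes passed for I-BET151, JQ1 and their mean. In that last setting leaving out 1 array gave 377 to 1042, 951 to 2205 and 1001 to 2316 genes, and with rounding dithered 0 to 420, 222 to 1081 and 194 to 1068, the lowest each time without CTRL 2 in the latter. Of the called genes above the median intensity, 200 of 213, 618 of 750 and 656 of 972 were called in all 6 fits without 1 array and without the dimmer genes.

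For I-BET151, JQ1 and their mean, leaving out the dimmest 25% of genes gave 798, 1733 and 2045 genes, an intensity trend with a robust prior 1806, 2617 and 3006 (and 6 between the compounds), and an adjusted p under 0.10 950, 2216 and 2713. Centring each array on its median gave 558 and 1457 genes for I-BET151 and JQ1, and an intensity trend alone 446 and 1377. An unadjusted p under 0.05 with a fold of 1.5 gave 708 genes for I-BET151 and 66 between the compounds. Apart from these, the cause was not tested. Quantile normalization, the mean of repeated rows, every row tested and array weights kept the counts within 1.5 times. Scalings moved the median of all genes by at most 0.0652.

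The values gave no sign that the replicate numbers pair the samples: deviations of same-numbered arrays correlated at -0.0160, -0.0260 and -0.0399. The labels do not say whether same-numbered pools shared a litter or culture day, so pairing is not ruled out. With the replicate block and no dimmer genes, 1098, 1974 and 2301 genes passed. With an estimated correlation 0 lists passed for either inhibitor, and without 1 array 13 to 17 passed for I-BET151 and 13 to 14 for JQ1. The correlation between the compounds was 0.739 to 0.856 without 1 array, lowest without I-BET151 1, and 0.586 and 0.620 with the controls split. For the mean of both inhibitors, oxidative phosphorylation genes passed no longer without CTRL 1 (0.210) and histone genes without CTRL 2 (0.298). Median centring shrank some medians of shifted lists more than 1.5 times: acinar genes under I-BET151 from -0.06 to -0.02, oxidative phosphorylation genes under I-BET151 from -0.10 to -0.07, and under JQ1 Myc and its growth targets from -0.16 to -0.09, duct genes from -0.15 to -0.09, p53 targets from -0.19 to -0.12 and S phase genes from -0.16 to -0.09. Array signal limits dim genes, whose steps of 1 unit are large on the log2 scale.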

Other observations

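The gene families below, the family members named and the test of structured short RNAs were chosen only after the data were seen; the tests of other short RNAs, of host genes and of gene span were fixed before their results. The bound fixed for other short RNAs was met, which by the fixed rule would have ruled out a general difference in their recovery. Of the 238 genes, 219 were microRNAs, and whether their rows measure the short form was not tested, so that test could not decide this. The reading of that test was changed 2 times after its result was seen, first for the dimness of microRNAs alone and then by a test of brighter microRNAs, whose criterion was set before its own result.

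Beyond the fixed lists, 270 families of at least 10 genes sharing a symbol stem were tested. Toll-like receptor genes, sensors of microbial products, had median log2 changes of -0.31 under I-BET151, which did not pass, and -0.58 under JQ1 (12 genes, camera adjusted p = 3.80e-05, and adjusted p = 0.950 with an estimated correlation). Tlr13, Tlr2 and Tlr3 fell under JQ1, by 1.96, 0.68 and 0.93. Annexin genes, which encode calcium-dependent membrane-binding proteins, had medians of -0.22 under I-BET151 and -0.38 under JQ1 (adjusted p = 0.00243 and 0.00188, and adjusted p = 0.866 and 0.950 with an estimated correlation). Anxa4 fell under both, and Anxa2 and Anxa5 under JQ1. The 12 gamma-A protocadherin genes, adhesion molecules of neurons, had medians of 0.55 and 0.48 (adjusted p = 0.00243 and 0.0147, and adjusted p = 0.866 and 0.950 with an estimated correlation), with none called. Their transcripts share exons, so they are not independent measurements. These medians kept their sign under quantile normalization and median centring. The 534 microRNA genes passed under I-BET151 with a median of 0.09 (adjusted p = 0.0256, and adjusted p = 0.866 with an estimated correlation), with none called. Among the collagen genes, Col8a1 and Col14a1 fell under both inhibitors and Col15a1 under JQ1, Col8a1 by 1.23 and 1.47.

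Small nucleolar RNA genes, which guide modification of ribosomal RNA, were higher in JQ1 than in I-BET151 arrays, in 82 of 97 genes, with a median difference of 0.260 (bootstrap interval 0.235 to 0.323). Only genes with a mean intensity above 20 were used for these, for the other short RNAs and for the host genes. Against control their medians were 0.327 for JQ1 and 0.0530 for I-BET151, with 0.317 and 0.328 in the JQ1 arrays and 0.0313 and 0.0961 in the I-BET151 arrays, and Snora34, Snora70, Snord22, Snord35b, Snord66 and Snord89 rose under JQ1. As symbol families of any intensity, Snord and Snora passed under JQ1 (camera adjusted p = 1.97e-08 and 0.00101, and adjusted p = 0.950 for each with an estimated correlation). The bootstrap intervals treat genes as independent. For higher transcription of the host genes, 18 host genes of the Snhg family and Gas5 had a median of 0.0153 (-0.0675 to 0.107). This argues against a matching rise in the transcripts of the hosts tested. Hosts outside this family were not tested, and array signal measures the amount of a transcript rather than its transcription. Higher transcription of other hosts therefore stays open. For a general difference in the recovery or labelling of short RNAs, the other 238 short RNA genes had a median of 0.00474 (-0.0409 to 0.0352). These genes, 219 of them microRNAs, registered shifts against control in both groups (0.218 and 0.0916 in the I-BET151 arrays, 0.240 and 0.111 in the JQ1 arrays, and 0.0431 in size in the controls). The 46 microRNAs at or above the lower quartile of small nucleolar RNA intensity had 0.0524 (-0.0437 to 0.129). This argues against a difference of 0.260 in the signal of microRNA rows but, just above the criterion of 0.05, leaves a smaller one open. Whether these rows measure mature microRNAs or longer precursors was not tested, so they cannot decide on the recovery of short RNAs. The 19 structured short RNA genes other than microRNAs, with a median intensity of 402, were also higher in JQ1, with a median of 0.143 (0.0298 to 0.336), so a difference between libraries in recovering structured short RNAs is a candidate explanation that these data leave open, beside an effect of the compound or its dose.

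A further hypothesis was that longer genes change differently from shorter ones. Over 11306 protein-coding genes above the median intensity, Spearman's rho of genomic span and log2 change was 0.209 and 0.146 in the I-BET151 arrays and 0.104 and 0.0404 in the JQ1 arrays. Dimmer genes were left out of this test. The control arrays, each against the other, gave -0.141 and 0.141, larger in size than the values of both JQ1 arrays. The smallest treated value, 0.0404, lies inside that range, so the test leaves open whether span matters.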
